A study of Homo sapiens with 13 samples.

How the data were processed

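Expression arrays of human Wilms tumors were analysed from the deposited table of values. Total RNA was prepared with Trizol, converted to cRNA and hybridized to Affymetrix 133A arrays, per the labels' protocols. The dye field of the labels names Cy3 and Cy5, although arrays of this kind are read in a single colour, and 1 value per probe set and tumor was used. The deposited values are intensities on a linear scale for 22277 probe sets, 62 of them controls. Their mean after trimming 2% at each end lay between 250.05 and 250.07 on every array, so the deposited intensities had been scaled per array to a common trimmed mean. The method that summarised probes into probe sets is not given in the sources used here.

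Tumors were grouped by the source name in the labels, 8 in Class 1 and 5 in Class 2, and replicate numbers follow accession order and only name a tumor. The columns of Class 1 replicate 7 and Class 2 replicate 2 held no values and were not used here, so the planned fits over 13 tumors were run on 11. What the classes stand for was not given in the labels. Array medians ran from 76.0 to 89.2, a ratio of 1.17 that exceeded the planned limit of 10%. Each array was therefore scaled to a common 75th percentile, values under the 20th percentile of the table (12.9) were raised to it, and log2 was taken (floor 3.69). Log2 medians then ran from 6.22 to 6.46 and interquartile ranges differed by up to 1.22 times, so no quantile step was added. Between 17.3% and 24.1% of values per array were at the floor, where differences between tumors cannot be seen.

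Probe sets were named through the platform's annotation table, whose symbols can be old. It pairs 19070 probe sets with 1 gene symbol and 1043 with several, and 2164 are unlisted there. Of the first, 19058 matched the RefSeq gene table (assembly GRCh38.p14) by Entrez identifier, and 0 symbols needed updating. No coordinates are printed, because the deposited values name no genome build. Each gene was represented by the probe set of highest mean among those paired with it alone. For 4304 genes with several probe sets, all of them had differences of 1 sign in 54.9%. Genes that tell the sex of a donor were left out of every test, which left 11939 genes.

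Class 2 was compared with Class 1 in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists, 24 in number, were tested with camera at a preset correlation of 0.01, and again with the correlation estimated and with fry, which tests a list by itself and not against other genes. List means per tumor were compared by an exact two-sided permutation test over all 330 splits of the 11 tumors into 7 and 4, for which the smallest p is 0.00303. The same test served the 3′ minus 5′ difference of the ACTB and GAPDH control probe sets, a measure of RNA quality, and the first 3 principal components of the 2000 most variable genes. Figures were drawn with matplotlib 3.10.9.

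The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the genes that passed, filled up by smallest p to 5 in each direction, up to 2 members of smallest p from each list without a passing member, and a fixed set of genes known in Wilms tumor or used as markers. LGR5, WIF1, CCND1, CD44 and FST were chosen after their values were seen. Lists covered Wnt/β-catenin targets, FGF/ERK feedback, IGF pathway, cell cycle, hypoxia, immediate early, interferon and retinoic acid response genes, imprinted genes, recurrently mutated Wilms tumor genes, kidney lineages (nephron progenitor, early nephron epithelium, podocyte, mature tubule) and other cell types (interstitial and stromal, skeletal muscle, smooth muscle, cartilage and bone, adipocyte, neural, T and B cell, macrophage and myeloid, endothelial, erythroid).

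Alternatives were quantile normalization, median centring, no floor with log2(value + 16), genes under the 25th percentile left out, the mean of a gene's probe sets, probe sets prone to cross-hybridization left out, all probe sets, a variance trend with robust eBayes, array weights, the 3′ to 5′ difference as a covariate, a fold change of at least 2, 500 or 5000 genes for the components, and each tumor left out in turn. Chosen after seeing the data were the deposited scaling, the average of Class 2 replicates 1 and 3, the removal of Class 1 replicate 1 with Class 2 replicate 5, and the permutation test of list means. A component was followed into each setting by its gene weights, one to one, and was given no value where the correlation of weights was under 0.5. This matching was settled after an earlier matching, which could pair 2 components with 1, had been seen to give the same value for both.

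The procedure was tested on simulated data for the comparison of Class 2 with Class 1, with 11939 genes of which 200 were changed, in 10 simulations. It recovered 30% of genes changed 2-fold, 76.4% changed 4-fold, 93% changed 8-fold and 96.8% changed 16-fold, and 5.43% of calls were false. The Wnt target list, when shifted, was found in 10 of 10 simulations. Data with no shifted list gave 1 list call over all simulations. Genes were simulated as independent of each other. In the tumors the estimated correlation was 0.20 within the Wnt target list and 0.72 within the skeletal muscle list. False list calls among correlated genes were therefore not measured by the simulations. The floor was not applied to the simulated values, so the recovered shares do not show what is found among genes at the floor. Each gene had the same spread in every simulated tumor, so outlying or alike tumors were not simulated either.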

Results

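Gene expression was measured in human Wilms tumors, an embryonal kidney cancer of childhood, with 1 Affymetrix 133A array per tumor. The labels divided 13 tumors into 8 of Class 1 and 5 of Class 2 and did not define the classes. Values were held for 7 Class 1 and 4 Class 2 tumors, and the comparison rested on these 11 arrays. The number of arrays limited the precision of every difference. Nothing in the labels said that the tumors came from separate patients, so the p-values measured only the spread between these samples, which may be technical in part. One Class 2 tumor, replicate 5, carried Class 3 in its genotype field and Class 2 in its source name. It was kept in Class 2. All differences are Class 2 minus Class 1 on the log2 scale of the scaled and floored intensities, so folds of dim genes are understated.

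The comparison asked which genes differed in expression between the classes. SULT1E1, the sulfotransferase that inactivates estrogens, was 15.6-fold higher in Class 2, with a log2 intensity of 8.66 ± 0.74 (SD, n = 4) against 4.70 ± 0.79 (SD, n = 7). BRINP2, a gene of the nervous system, was higher in Class 2 at 5.00 ± 0.31 (SD, n = 4) against 3.76 ± 0.18 (SD, n = 7). MICA, a stress-induced ligand of the natural killer cell receptor NKG2D, was lower in Class 2 at 4.07 ± 0.55 (SD, n = 4) against 6.51 ± 0.23 (SD, n = 7). For each of these genes all 4 Class 2 tumors lay on one side of all 7 Class 1 tumors.

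**Figure D1:**
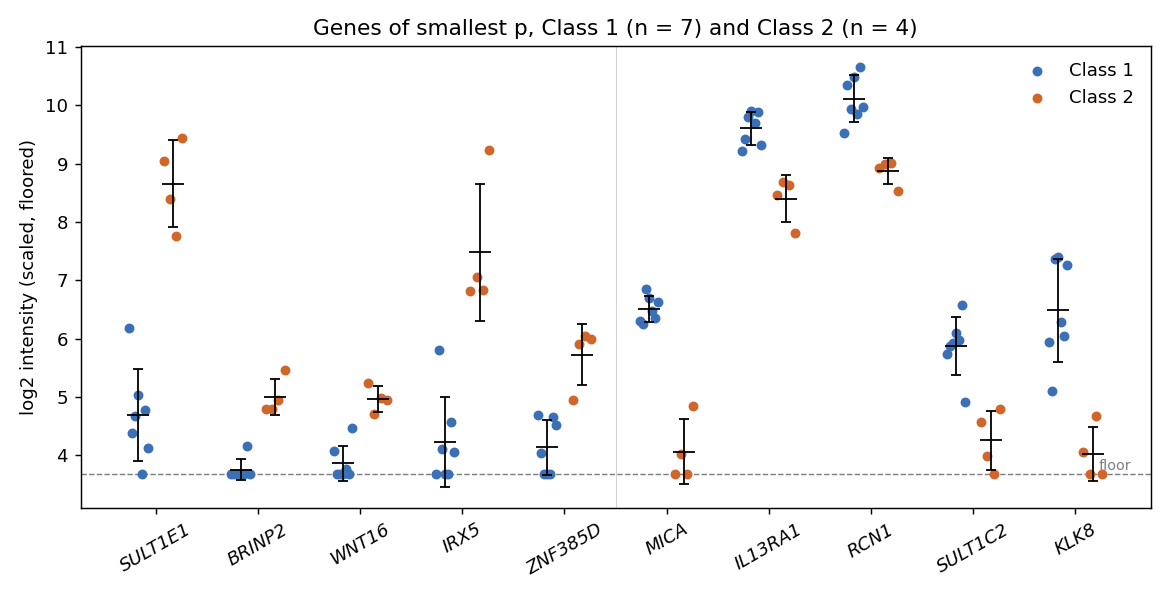
Log2 intensity (vertical axis) of the genes with the smallest p in each direction, by class, with 1 point per tumor, bars for mean ± SD and a dashed line at the floor of 3.69. SULT1E1 averaged 8.66 in Class 2 against 4.70 in Class 1, and MICA averaged 4.07 against 6.51.

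The log2 differences were 3.96 for SULT1E1 (SE 0.46, limma adjusted p = 0.0282), 1.24 for BRINP2 (SE 0.15, limma adjusted p = 0.0282) and -2.44 for MICA (SE 0.22, limma adjusted p = 0.00857). These were the 3 of 11939 genes that passed limma with Benjamini-Hochberg adjustment, 2 higher and 1 lower in Class 2. BRINP2 stood above the floor in 1 of 7 Class 1 tumors, and MICA in 2 of 4 Class 2 tumors, so both differences were measured against a group at or near the floor. A further probe set, paired with both MICA and MICB, differed by -1.72 (SE 0.42) with a limma adjusted p of 0.465 over all probe sets. With the 3′ to 5′ signal difference of each array as a covariate limma passed 0 genes, against 558 at an unadjusted p under 0.05. Leaving out 1 tumor gave 0 genes without Class 2 replicate 1 or without Class 2 replicate 3, with 781 and 759 at an unadjusted p under 0.05. It gave 1 without Class 1 replicate 3, 4 or 5, 5 without Class 1 replicate 6 and 8 without Class 1 replicate 8. The differences stayed near their size in these runs, from -2.72 to -2.31 for MICA, 3.71 to 4.26 for SULT1E1 and 1.11 to 1.31 for BRINP2, with limma adjusted p of up to 0.0755, 0.147 and 0.115. Without Class 2 replicate 5, whose genotype field reads Class 3, MICA and BRINP2 passed and SULT1E1 did not (limma adjusted p = 0.117).

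Among genes that did not pass, those with the smallest p and higher values in Class 2 were WNT16, a secreted Wnt ligand, with a difference of 1.11, the homeobox gene IRX5 with 3.25 and ZNF385D with 1.59. Those with lower values were IL13RA1, a subunit of the interleukin 13 receptor, at -1.21, RCN1 at -1.24, SULT1C2 at -1.61 and the protease gene KLK8 at -2.46. Their limma adjusted p ranged from 0.215 to 0.391. At an unadjusted p under 0.05 stood 844 genes, 370 with higher and 474 with lower values in Class 2, where chance gives 597. The classes did not overlap for 130 genes, 1.09% of those tested, where chance gives 0.606%. Neither count was set against other splits of the tumors, and genes vary together, so an excess over chance was not tested.

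Of the 20 measured Wnt/β-catenin target genes 17 had positive and 3 negative differences, with a mean of 1.04 and a median of 0.73, higher in Class 2 by camera (adjusted p = 1.56e-05). The call was lost with an estimated correlation between genes, at a camera adjusted p of 0.803 (unadjusted p = 0.0362). Without Class 2 replicate 5 the mean was 0.72 (camera adjusted p = 0.00564 at the preset correlation). List scores, the mean centred log2 value of the members per tumor, overlapped between the classes. They ran from -0.97 to 0.46 in Class 1 and from 0.05 to 1.61 in Class 2. DKK1, a secreted Wnt inhibitor, differed by 3.21 (SE 0.76) and was the 1 member that passed when adjusted over the list alone (limma adjusted p = 0.0365), against 0 members over all genes tested. BAMBI, a pseudoreceptor of TGF-β signalling, had a difference of 0.98 and LEF1, a transcription factor that binds β-catenin, one of 0.57, and of 0.93 without Class 2 replicate 4. Chosen after their values were seen, WIF1 had a difference of 3.60, LGR5, a receptor of R-spondins, 3.26, FST 2.27 and CCND1 1.41, while CD44 went the other way at -1.55. CTNNB1, which encodes β-catenin itself, differed by 0.09 (SE 0.30), but by -0.00515 with the 3′ to 5′ covariate. For the list, fry gave an adjusted p of 0.379 for a shift in one direction and 0.0127 for changes in either direction. An exact permutation test of the list mean over tumors gave p = 0.0333 and an adjusted p of 0.4. The 3′ minus 5′ difference of the control probe sets was 0.33 ± 0.23 (SD, n = 7) in Class 1 and 0.10 ± 0.23 (SD, n = 4) in Class 2 (exact permutation p = 0.161).

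**Figure D2:**
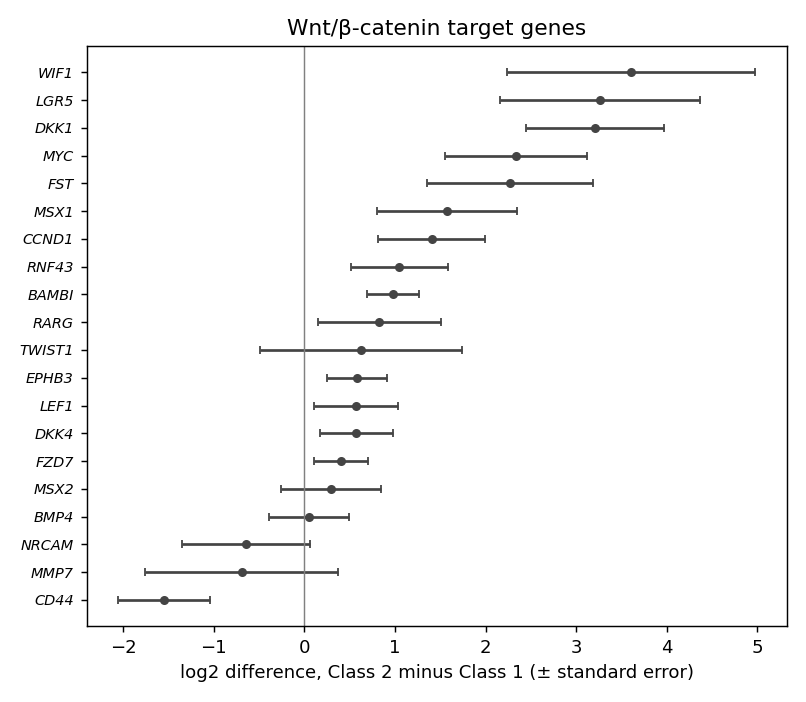
Class 2 minus Class 1 log2 difference (horizontal axis) of each measured Wnt/β-catenin target gene, with points for the difference and bars for its standard error. Of 20 members 17 lie above 0, DKK1 at 3.21, and CD44 lies at -1.55.

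Interstitial and stromal genes had positive differences in 21 of 25 members, with a mean of 0.68 (camera adjusted p = 0.0027). The call was lost with an estimated correlation (adjusted p = 0.949), and the mean was 0.42 without Class 1 replicate 3. No member passed over all genes or over the list alone, and 0 had an unadjusted limma p under 0.05. PDGFRA, the platelet-derived growth factor receptor α, had a difference of 1.71 (SE 0.95), and COL1A2, a chain of type I collagen, 0.86 (SE 0.54). Stromal scores, the mean of the centred log2 values of the list, spread from -1.77 to 1.46 in Class 1 and from 0.08 to 0.60 in Class 2. The Wnt target scores and the stromal scores were both higher on average in Class 2.

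FGF/ERK feedback genes had positive differences in 13 of 18 members, with a mean of 0.48 (camera adjusted p = 0.00955), and an adjusted p of 0.949 with an estimated correlation. The ephrin receptor gene EPHA4 had a difference of 1.90 and SPRY1, an inhibitor of receptor tyrosine kinase signalling, 1.13. Neither passed over the list alone or over all genes. MYC, with a difference of 2.33, and CCND1, with 1.41, are members of both this list and the Wnt targets. The FGF/ERK list was not tested without them, so it is not evidence separate from the Wnt targets. The camera adjusted p of the list was 0.0825 without Class 1 replicate 1 and 0.0691 without Class 2 replicate 1.

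Skeletal muscle genes had positive differences in 26 of 33 members, with a mean of 0.77 (camera adjusted p = 0.033). With an estimated correlation the adjusted p was 0.949, and no member passed over the list alone or over all genes. MYOG, a myogenic transcription factor, had a difference of 1.38 (SE 0.91), the cardiac actin gene ACTC1 1.96 (SE 1.60) and the desmin gene DES 0.25 (SE 1.01), and the direction of DES turned under other settings. Without Class 2 replicate 5 MYOG had 0.62 and ACTC1 0.80, and without Class 2 replicate 3 ACTC1 had 3.02. A few tumors carried the signal, with muscle scores of 3.38 in Class 2 replicate 5, 0.69 in Class 2 replicate 4 and 3.12 in Class 1 replicate 2, while the other 8 tumors lay between -1.22 and -0.18. Without Class 2 replicate 5 the mean difference was -0.19 (camera adjusted p = 0.634), and without Class 1 replicate 2 it was 1.34. The camera adjusted p was 0.123, 0.0876, 0.12, 0.0935 and 0.164 without Class 1 replicate 1, 4, 5, 6 and 8, and 0.0729 without Class 2 replicate 4. It was 0.0545 with quantile normalization, 0.0513 without probe sets prone to cross-hybridization and 0.0674 with the deposited scaling. With array weights the mean was -0.32, and with the 3′ to 5′ covariate it was 0.06.

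**Figure D3:**
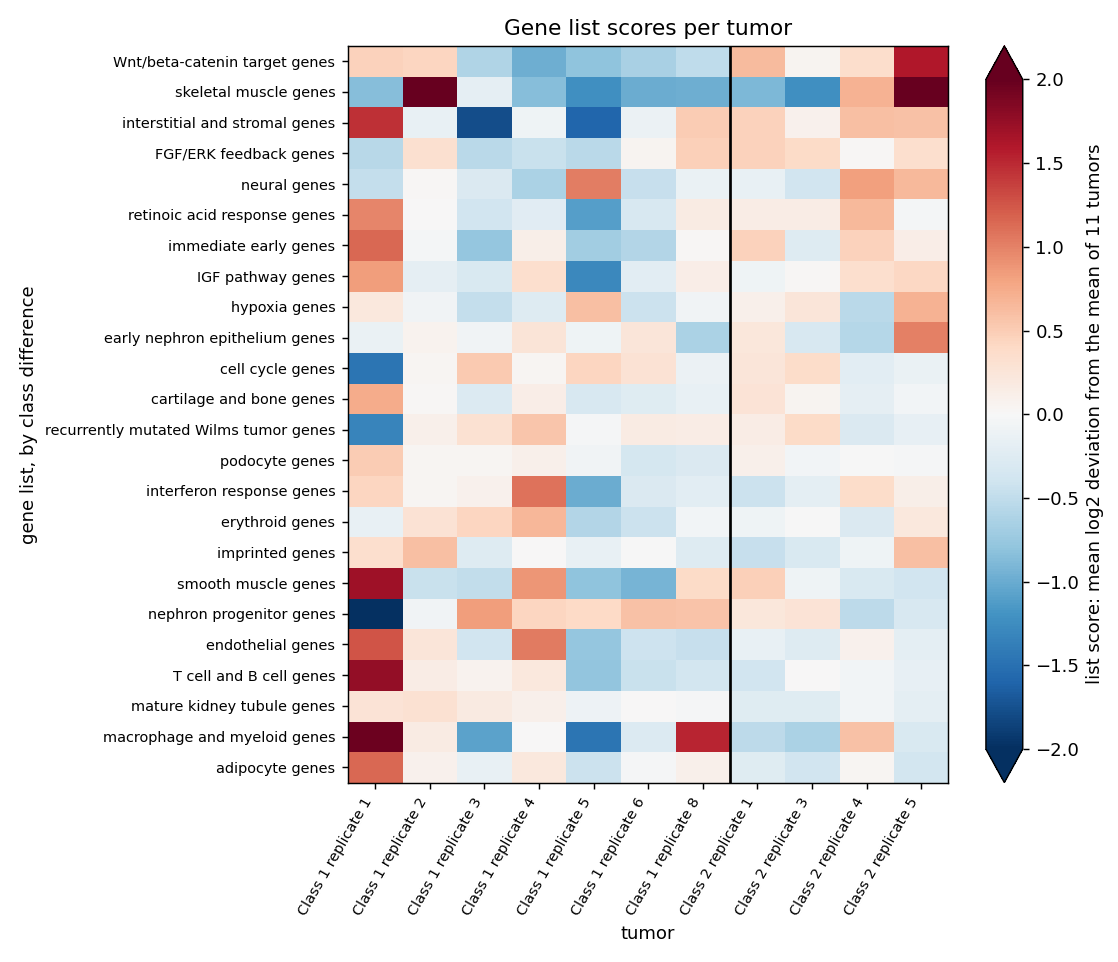
Score of each gene list (rows) in each of the 11 tumors (columns, by class), as the mean centred log2 value of its members, with colours limited to ±2. Muscle scores reach 3.12 in Class 1 replicate 2 and 3.38 in Class 2 replicate 5, and Class 1 replicate 1 has a nephron progenitor score of -2.39.

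None of the 4 kidney lineage lists passed camera. Mature kidney tubule genes had negative differences in 15 of 17 members, with a mean of -0.29 (camera adjusted p = 0.182, fry adjusted p = 0.0206). The adjusted p was 0.803 with an estimated correlation and 0.364 by exact permutation. FBP1, an enzyme of gluconeogenesis, had a difference of -1.14. Early nephron epithelium genes had a mean of 0.14 and a median of -0.24, and 2 of 20 members passed when adjusted over the list alone, IRX5 at 3.25 and SOX9, a transcription factor of progenitor and cartilage cells, at 2.08 (limma adjusted p = 0.003 and 0.0149). SOX9 also passed over the cartilage and bone list alone, whose mean was 0.03. fry gave the early nephron list an adjusted p of 0.0225 for changes in either direction. Nephron progenitor genes had a mean of -0.14 and a median of -0.14, where camera gave the upward direction (adjusted p = 0.971), and the progenitor factor SIX2 had a difference of 0.42 (SE 0.50), and of 0.0775 without Class 1 replicate 1. In podocyte genes, with a mean of 0.00299, a median of -0.09 and a downward camera direction, CLIC5 had a difference of -1.29 and PODXL -0.65. CLIC5 reached -3.06 without Class 2 replicate 1, since another of its probe sets then had the highest mean, as it did without each other Class 2 tumor in turn.

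Over the 24 lists camera passed 4, all higher in Class 2. With the correlation estimated 0 passed, with 1 list at an unadjusted p under 0.05. fry passed 1 for direction and 2 for either direction, and the exact permutation test passed 0, with 2 at an unadjusted p under 0.05. Without Class 1 replicate 5 camera passed 7 lists. WT1, a tumor suppressor of this cancer, had a difference of -0.87 (SE 1.35), which ran from -1.83 without Class 1 replicate 1 to -0.39 without Class 2 replicate 5. MYCN had a difference of 0.68 (SE 1.03), and of -0.0696 without Class 1 replicate 1.

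The main variation between tumors did not follow the classes. Component 1 of the 2000 most variable genes held 31.1% of the variance, with a class difference of 17.7 (exact permutation p = 0.4), which fell to 7.79 without Class 1 replicate 3 or without Class 2 replicate 4. Component 2 held 16.3% and separated the class means by 32.6 (exact permutation p = 0.0121, adjusted p = 0.0364 over 3 components). IRX5, LGR5 and WIF1 and muscle genes such as ACTC1 were among the 20 genes of largest positive weight on component 2. WIF1 was also among the 20 of largest positive weight on component 1. Component 3 held 12.6% (adjusted p = 0.821). The separation on component 2 had an adjusted p of 0.259 over the 500 and 0.0727 over the 5000 most variable genes. Without 1 tumor it reached 0.0714 and 0.1 for Class 1 replicates 3 and 4, and 0.075, 0.125, 0.125 and 0.075 for Class 2 replicates 1, 3, 4 and 5. Without Class 1 replicate 1 component 2 had no counterpart of its own, since the leading component there correlated with both component 1 (r = 0.826 in size) and component 2 (r = 0.692 in size) over gene weights. That component separated the classes by 40.4, which did not pass over 3 components (exact permutation p = 0.0238, adjusted p = 0.0714).

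Correlations between tumors over genes ran from 0.825 to 0.937 within Class 1, from 0.924 to 0.976 within Class 2 and from 0.869 to 0.951 between the classes. Class 2 replicates 1 and 3 were the most alike pair, at 0.976. Their titles in the labels carry consecutive numbers, whose meaning is not given, so they may not be independent samples. When they were averaged into 1 sample limma passed 0 genes, with 727 at an unadjusted p under 0.05.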

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

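Chosen after their results were seen were the test of degraded RNA for Class 1 replicate 1 and the use of the probe set shared by MICA and MICB, first left out because it names 2 genes and then taken up when its value was known. The bounds asked of the RNA quality value, the kidney tubule score and the BRINP2 difference were also set after their values were seen. Of 158 groups of values, 21 held a tumor far from the rest of its class by Dixon's criterion, where chance gives 7.9. Class 1 replicate 1 was that tumor in 12 of the 21. The chance value takes no account of the floor. BRINP2 in Class 1 replicate 6 and MYOG in Class 1 replicate 2 stood out because all other Class 1 tumors were at the floor.

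Class 1 replicate 1 stood apart from the other Class 1 tumors in several lists and genes. Its nephron progenitor score was -2.39, its cell cycle score -1.45 and its score for recurrently mutated Wilms tumor genes -1.32, all below the rest, while its scores for T and B cells (1.75), adipocytes (1.14) and cartilage and bone (0.75) were above. WT1 had a log2 intensity of 4.62 in this tumor, where the nearest Class 1 tumor had 10.7. MYCN was at 5.23, SIX2 at 8.36 and the neuronal gene STMN2 at 8.23. Its mean correlation with the other tumors was 0.866 and its position on component 1 was 64.8.

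Degraded RNA stays open as a source of this tumor's distance, since its 3′ minus 5′ difference of 0.436 lay below the 0.768 of 1 other tumor but above those of the remaining 9 (SD of the others 0.247). Normal kidney in the specimen also stays open, as its mature kidney tubule score of 0.273 lay below their highest, 0.307, by less than their SD of 0.181. The podocyte score of this tumor, 0.515, lay above the highest of the others, 0.102, and was not part of that test. A stroma-rich specimen remains a candidate explanation, since its stromal score of 1.46 exceeded the highest of the others, 0.603. Its smooth muscle, macrophage and endothelial scores also lay above all others. The tumor lay above all others in 11 lists, below all in 4 and within their range in 9. A score above the others therefore does not single out stroma. The title of Class 1 replicate 1 in the labels begins with other letters than those of the other 10 tumors with values. What these letters mean is not given, and beyond tissue content no biological explanation was tested.

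The higher Wnt/β-catenin targets in Class 2, with a mean difference of 1.04, were weighed against 3 technical or compositional explanations. Class 1 replicate 1 had the highest Wnt score of its class (0.463) and so worked against the difference, which was 1.18 (SE 0.366) without it, above 0.518, the size that would mark the loss of 50%. With the stromal score as a covariate it was 0.818 (SE 0.383), and with the 3′ to 5′ difference as a covariate 0.849 (SE 0.441). Both lay within 1 SE of that bound, so stromal content and RNA quality may account for a part and stay open, as does the class itself, as untested. The difference also leaned on Class 2 replicate 5, whose genotype field reads Class 3, with 0.72 and a camera adjusted p of 0.00564 without it. Over all 11 tumors the adjusted p was 0.803 by camera with an estimated correlation, 0.379 by fry and 0.4 by exact permutation.

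The genes that passed were weighed against the floor and against reliance on 1 probe set. With no floor the limma adjusted p was 0.00603 for MICA and 0.00603 for SULT1E1, so these calls did not need the floor. For BRINP2 it was 0.252. The 16 added before log2 in that run also compresses low values. A part of such compression in the MICA call, whose difference was then -1.80 (SE 0.206), was therefore not tested. The BRINP2 difference was 1.03 (SE 0.198) with no floor and 1.24 (SE 0.146) with it, so the call ended with a smaller difference and a larger SE, and the part of the floor stays open. For MICA the probe set it shares with MICB fell by 1.72 (SE 0.42), over 50% of the -2.44 of its own probe set, which argues against a fault of 1 probe set, although MICB could contribute to that value. SULT1E1 and BRINP2 had 0 other probe sets each, so a fault of their probe set cannot be told apart from a change of the gene. The SULT1E1 probe set is of the kind prone to cross-hybridization, so the gene was absent from the run without such probe sets. A sequence variant under the probes was not tested for any of them.

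For the count of 3 genes, 4 of 100 splits drawn from the 330 of the 11 tumors into 7 and 4 gave as many, the real one included, a share under 0.05 by 1 split. The other splits were a random draw and 1 more such split would have reached the 0.05 bound, so chance was not excluded. The count also rested on Class 2 replicates 1 and 3, the most alike pair, being independent samples, as with them averaged it was 0. The highest other split gave 609 genes. It set Class 1 replicates 1 and 5 with Class 2 replicates 4 and 5. This points to a structure of the samples that was not tested. The titles of these tumors in the labels, apart from that of Class 2 replicate 5, carry numbers that lie close together across the classes. What the numbers mean is not given. For the count of 4 lists, 75 of 100 splits gave as many, with 14 as the highest other, so chance could not be excluded.

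Class 1 replicate 2 lay above the other Class 1 tumors in skeletal muscle score (3.12), in MYOG (log2 intensity 6.63) and in IRX5 (5.80). In Class 1 replicate 5 the neural score was 1.03, above the rest of its class. Class 1 replicate 6 had the highest Class 1 values of BRINP2 (4.17) and SOX5 (5.62). In Class 2 replicate 5, IRX5 was at 9.23 and MYC at 10.4, above the other Class 2 tumors. ZNF385D was at 4.95 in Class 2 replicate 1, below the others of that class.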

How the results depend on the processing

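Chosen after the data were seen were the deposited scaling, the average of Class 2 replicates 1 and 3, the removal of Class 1 replicate 1 with Class 2 replicate 5, the permutation test of list means and the matching of components. No paired analysis was possible because replicate numbers follow accession order only. Signal at the floor limits what can be seen of dim genes. Of 50 named genes 47 kept their direction under every alternative run, as did 10 of 24 lists, among them the Wnt targets, stromal and FGF/ERK feedback lists. Most of these genes were named for a small p in these data or after their values were seen, which favours a stable direction. The 3 that turned, CTNNB1, MYCN and DES, came from the fixed set. List means were the same by construction with an estimated correlation, fry and the permutation test. Those runs could not turn a list. The median difference of all genes stayed within 0.1 of 0 throughout. Unless construction shows it, as in runs with fewer tumors or genes, the cause was not tested.

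The count of 3 genes (2 higher, 1 lower) became 0 with the 3′ to 5′ covariate and 0 with Class 2 replicates 1 and 3 averaged. It became 5 with Class 1 replicate 1 and Class 2 replicate 5 left out together, and ran from 0 to 8 without 1 tumor. The differences of MICA, SULT1E1 and BRINP2 were -2.51, 4.26 and 1.13 with the covariate and -2.37, 3.94 and 1.31 with the average. They kept their direction in every alternative run, and no longer passed in 4 of 23 for MICA, 10 of 22 for SULT1E1 and 14 of 22 for BRINP2. Quantile normalization gave 3 higher and 1 lower, and median centring 1 and 1. The count of 4 lists became 0 with an estimated correlation, 1 with fry and 0 with the exact permutation, and ran from 3 to 7 without 1 tumor. The class difference on component 2 was 16.9 over 500 and 36.4 over 5000 genes, where it no longer passed, and 30.6 to 37.3 without 1 tumor. On component 3 it turned to -18.1 over 5000 genes and ran from -3.97 to 12.6 without 1 tumor. Component 3 had no counterpart over 500 genes or without Class 1 replicate 5. The RNA quality difference did not pass in any run, with -0.293 to -0.142 without 1 tumor.

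Reversed means with the 3′ to 5′ covariate were smooth muscle 0.42, neural -0.087, T and B cell 0.0449, endothelial 0.22, erythroid 0.15 and interferon 0.27, with CTNNB1 at -0.00515 and DES at -0.19. Array weights turned skeletal muscle to -0.32, smooth muscle to 0.13 and DES to -0.55. With Class 1 replicate 1 and Class 2 replicate 5 left out together, skeletal muscle was -0.29, early nephron -0.18, smooth muscle 0.27, T and B cell 0.0600, endothelial 0.0239, cell cycle -0.069, recurrently mutated genes -0.13, MYCN -0.0169 and DES -0.45. Averaging Class 2 replicates 1 and 3 turned podocyte to -0.00273, cartilage and bone to -0.0137, imprinted to 0.00252, recurrently mutated genes to -0.0543 and interferon to 0.0367. Podocyte was also -0.0119 with median centring, -0.0789 with no floor, -0.0668 without dim genes, -0.033 with the mean of probe sets and -0.0353 without cross-hybridizing probe sets, where smooth muscle was 0.0157 and cartilage and bone -0.00791.

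Without 1 tumor the ranges that crossed 0 were -0.19 to 1.34 for skeletal muscle, -0.55 to 0.00607 for nephron progenitor, -0.17 to 0.36 for early nephron, -0.14 to 0.12 for podocyte, -0.29 to 0.17 for smooth muscle, -0.0389 to 0.17 for cartilage and bone, -0.38 to 0.04996 for T and B cell, -0.16 to 0.0412 for erythroid, -0.14 to 0.20 for cell cycle, -0.33 to 0.0295 for imprinted, -0.19 to 0.13 for recurrently mutated and -0.23 to 0.12 for interferon genes. CTNNB1 ran from -0.0373 to 0.26, MYCN from -0.0696 to 0.94 and DES from -0.73 to 0.82.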

Other observations

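The other cell type and pathway lists did not pass camera, with adjusted p from 0.131 to 0.851, and are given as mean log2 differences. Macrophage and myeloid genes had negative differences in 16 of 18 members, with a mean of -0.34 that ran from -0.61 without Class 2 replicate 4 to -0.0336 without Class 1 replicate 1. Adipocyte genes had a mean of -0.38, T and B cell genes -0.23, endothelial genes -0.20, smooth muscle genes -0.11 and erythroid genes -0.06. Without Class 1 replicate 1 the adipocyte mean was -0.21 and the endothelial mean -0.000893, and over all runs without 1 tumor they reached -0.46 and -0.34. VWF, a blood clotting protein made by endothelial cells, had a difference of -1.25. Neural genes had a mean of 0.37 with a median near 0 and a range of 0.17 to 0.57 without 1 tumor, and TUBB3, a neuronal tubulin, one of 1.07 and STMN2 one of 2.64.

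Among pathway lists, retinoic acid response genes had a mean of 0.36, with CYP26A1, which breaks down retinoic acid, at 1.65 and STRA6, a retinol transporter, at 1.03. Without 1 tumor the retinoic acid mean ran from 0.19 to 0.54 and the immediate early mean from 0.20 to 0.53. Immediate early genes had a mean of 0.32, IGF pathway genes 0.27 with IGF1R at 1.46, hypoxia genes 0.20 and cell cycle genes 0.10 with MCM5 at 0.61. Without 1 tumor the IGF mean ran from 0.0761 (Class 1 replicate 5) to 0.43 (Class 1 replicate 1) and the hypoxia mean from 0.0104 (Class 2 replicate 5) to 0.42 (Class 2 replicate 4). Interferon response genes had a mean of -0.05 with OAS1 at -1.25, and imprinted genes -0.10 with DIRAS3 at 1.65 and MAGEL2 at -1.54, or -0.93 without Class 2 replicate 1. Recurrently mutated Wilms tumor genes had a mean of 0.03, with TRIM28 at 0.60, where all 4 Class 2 tumors lay above the 7 Class 1 tumors. None of these genes passed limma over all genes tested.

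Some of these lists passed camera at the preset correlation under other settings, mostly when 1 tumor was left out. All 11 tumors with an estimated correlation gave each of them a camera adjusted p of 0.949. Without Class 1 replicate 5 the adjusted p was 0.0333 for neural, cell cycle and hypoxia genes and 0.041 for macrophage and myeloid genes. Without Class 2 replicate 4 it was 0.0345 for macrophage and myeloid and 0.00282 for hypoxia genes, and without Class 2 replicate 3 it was 0.0469 for neural and 0.0173 for immediate early genes. Immediate early genes reached 0.00485 without Class 1 replicate 1 and 0.0494 without Class 2 replicate 5, and cell cycle genes 0.0353 and 0.0494 without Class 1 replicate 3 and Class 2 replicate 5. Immediate early genes also passed with array weights (0.0402) and with the 3′ to 5′ covariate (0.0103). With Class 1 replicate 1 and Class 2 replicate 5 left out together, a setting chosen after the data were seen, immediate early genes reached 0.0012 and retinoic acid response genes 0.0202.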
